A study of Paraburkholderia xenovorans with 12 samples.

How the data were processed

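The bacterium Paraburkholderia xenovorans LB400, a soil strain that grows on biphenyl and degrades polychlorinated biphenyls, was grown in 30 mL of K1 medium with 0.76 g/L biphenyl and 0.9 g of a black carbon. Per the labels, the black carbon was granular activated carbon (GAC) or a biochar made from corn kernels in a small or a large size. The treatment codes SB and LB were read as the small and the large kernel biochar, since the design text lists these sizes and the labels do not spell out the codes. RNA was taken from suspended cells and from attached cells, depleted of ribosomal RNA with custom probes, and 228 ng per sample went into a stranded library. The 12 libraries form 6 groups of 2, from 3 materials and 2 fractions. The labels number the replicates but do not say that they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

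The main file holds counts that the authors deposited as whole numbers per locus tag, the identifier of 1 annotated gene. Per the submitters' processing notes, fastp, HISAT2, featureCounts and DESeq2 were used, and their versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Reads from overlapping or near-identical genes can therefore not be assigned with certainty. There are also 4 result tables that the authors deposited, 1 for attached against suspended cells and 3 for pairs of materials in attached cells. Per the file headers, each deposited table gives a log2 fold change, its standard error, a Wald score that is the log2 fold change divided by that error, and a p-value with its adjusted value. A refit with DESeq2 on the 12 libraries without a material term, or on the 4 attached libraries of a pair, gave 100% of the deposited log2 fold changes to within 0.01. In the deposited table of attached against suspended cells, 237 tags with a mean above 0 have no p-value. Every column of values belonged to a named sample or comparison, so the number of columns of no sample was 0.

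The count table lists 9044 tags, of which 4609 carry the letter A, 3047 the letter B and 1388 the letter C. The files do not pair tags with gene names, products or replicons, and no annotation was used here. The gene lists, the genes around the biphenyl dioxygenase gene and the removal of ribosomal and transfer RNA genes that had been planned were therefore not analysed here. Among the 9044 tags, 86 have an R before their number, a form that the files do not explain. These tags held between 65.5% and 75.1% of a library's counts.

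Counts were tested with edgeR 4.0.16 in R 4.3.3. Tags were kept by filterByExpr over the 6 groups, which left 8662 tags and removed 382. Libraries were scaled by TMM, a model of 6 group means was fitted to all 12 libraries with 6 residual degrees of freedom, and contrasts were tested with the quasi-likelihood F test. Adjusted p-values follow Benjamini-Hochberg over all tags of a comparison, and a tag is called changed at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM is the count scaled to the TMM-adjusted library size, and log2 CPM used a prior count of 2. There were 13 comparisons: attached minus suspended cells averaged over the materials and within each material, each pair of materials within each fraction, and each pair of materials for the difference of their attachment effects. The groups, comparisons, test and rule for naming tags were fixed before the data were examined.

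Named tags are those with the largest positive and negative log2 fold changes among changed tags with a mean of at least 10 CPM over the 12 libraries and with every library of one side above every library of the other, within each material for the averaged comparison. The fixed rule also asked for a product name and allowed longer lists. Without names, at most 2 tags in each direction are printed for a comparison, and the rest are described by counts and by runs of neighbouring tag numbers. Within single materials and in suspended cells fewer are printed. A run is at least 4 tested tags in tag order, all changed in 1 direction. Runs were set against 1000 shuffles of the calls within each letter, leaving out the R-numbered tags.

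The procedure was checked on simulated counts drawn from the means and library sizes of the real samples, with 200 tags changed by 2-fold or 4-fold. For attached minus suspended averaged over the materials, it called 58% of the 2-fold and 91% of the 4-fold changes, and 6 of its 155 calls were false. For attached cells the calls were 2% and 51% for SB minus GAC, 6% and 58% for LB minus GAC, and 2% and 64% for SB minus LB. In the same order, 2 of 55, 7 of 72 and 4 of 70 calls were false, and 1 further call for LB minus GAC had the wrong sign. The simulation gave every group the spread pooled over all 12 libraries, a common biological coefficient of variation of 0.322. Most 2-fold differences between materials would thus be missed at that pooled spread. Within the GAC and SB groups alone the coefficient was lower, at 0.123 to 0.19, and this spread was not simulated. Total counts ranged from 16040132 to 27664742 per library, and from 5537547 to 7843375 outside the R-numbered tags.

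Alternatives were DESeq2 size factors in place of TMM, no low-count filter, the Wald test of DESeq2 1.42.0, the replicate number as a block, a fit of only the libraries compared, and leaving out each library in turn. Further alternatives were chosen after seeing the data: leaving out both LB libraries numbered 1, leaving out both LB libraries numbered 2 or 1 suspended library each of GAC and SB, leaving out the R-numbered tags, and separate fits for 6 further comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.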

Results

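Transcripts of Paraburkholderia xenovorans LB400 were counted in 12 RNA-seq libraries, 2 for each of 6 groups: suspended and attached cells from cultures with granular activated carbon (GAC), large kernel biochar (LB) or small kernel biochar (SB). The design asked how the feedstock of a black carbon affects attachment and activity of the cells. Total counts were lowest in attached LB replicate 1, at 16040132, and highest in attached GAC replicate 1, at 27664742. Tags with an R before their number took 70.9% ± 2.81 of the counts in attached and 73.0% ± 2.12 in suspended libraries (SD over all materials, n = 6). This difference was not separated from the spread within materials (two-sided exact permutation test within materials, 216 permutations, p = 0.111). The group mean was lower in attached than in suspended cells with each material, at 72.46% against 73.55% with GAC, 68.39% against 70.84% with LB and 71.78% against 74.5% with SB. The remaining tags had between 5537547 and 7843375 counts per library.

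All suspended libraries lay below all attached ones along principal component 2 of the log2 CPM values, which held 20.8% of the variance. Suspended LB replicate 1 was the highest suspended library, at 1.59, and attached SB replicate 1 the lowest attached one, at 15.5. Component 1, with 40.4%, set both LB libraries numbered 1 apart from the other 10. Replicates correlated across tags at 0.980 to 0.986 in the 4 GAC and SB groups, at 0.893 in attached LB and at 0.863 in suspended LB, where tags are not independent replicates. The SD of the log2 difference between replicates was 1.08 in attached and 1.25 in suspended LB, against 0.403 to 0.504 in the other groups. No pair of replicates was identical, and in each group at least 31.0% of tags differed beyond the 95% limits of counting error. All groups share 1 estimate of the spread: the common biological coefficient of variation was 0.322 over all 12 libraries and 0.156 without both LB libraries numbered 1. The number of changed tags in each comparison is also given without both LB libraries numbered 1, an alternative chosen after seeing the data.

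**Figure D1:**
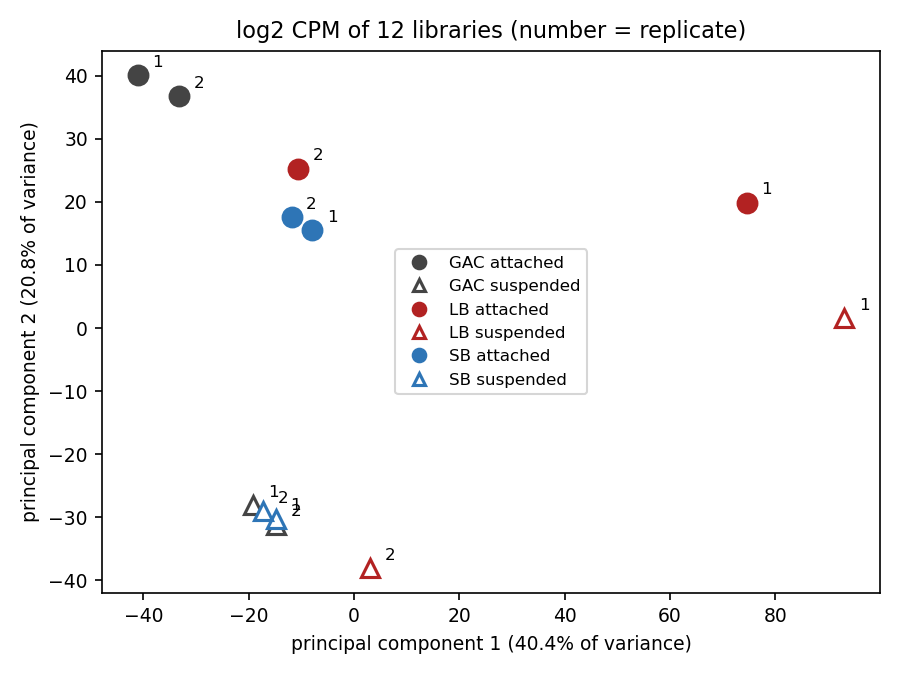
Principal components 1 (40.4% of the variance) and 2 (20.8%) of log2 CPM for the 12 libraries, where each point is a library, colour is the material, filled circles are attached cells, open triangles are suspended cells and the number is the replicate. Both LB libraries numbered 1 lie at the right, with component 1 values of 74.6 and 93.1, and all other libraries lie at or below 3.03.

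Attachment went with higher levels of more tags than lower ones. Averaged over the 3 materials, 645 tags were higher and 405 lower in attached than in suspended cells, 1050 of the 8662 tested (12.1%). Of these, 891 had the same sign in all 3 materials. The tags were called on the mean of the same materials, which favours a shared sign, and no reference value was computed. A fit with the material left out called 352 tags. The authors' deposited table calls 744 tags, 450 higher and 294 lower, of which 657 were called here in the same direction. Bxe_A1423 was 35.7-fold higher in attached cells (log2 fold change 5.16, SE 0.32, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 3.12e-05). Its level went from 7.89 ± 2.48 to 172 ± 75.9 CPM with GAC and from 10.95 ± 3.45 to 413 ± 150 CPM with SB (SD, n = 2 per group). The neighbouring tag Bxe_A1422 rose by 5.15 on the log2 scale (SE 0.25), and both belong to a run of 7 neighbouring tags with a median log2 fold change of 4.47. Bxe_B0675 was 68.1-fold lower in attached cells (log2 fold change -6.09, SE 0.30, edgeR adjusted p = 1.02e-05), from 367 ± 200 to 1.72 ± 0.639 CPM with LB (SD, n = 2 per group). Bxe_B0673, from the same run of 4 tags, fell by 5.97 on the log2 scale (SE 0.40), and by 6.66 without attached GAC replicate 2. Without both LB libraries numbered 1 the count was 2592, and 1035 of the 1050 tags were called again. Leaving out single libraries moved the count by over 1.5 times for 8 of the 12, between 548 without suspended GAC replicate 2 and 1670 without suspended LB replicate 1.

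Changed tags often lay side by side. Of 1045 changed tags without an R, 389 (37.2%) lay in 63 runs of at least 4 neighbours, 44 of them higher and 19 lower in attached cells, against a mean of 1.29 and at most 13 tags in 1000 shuffles (permutation p = 0.001, the smallest these shuffles can give). The longest higher run had 25 tags of the A series, with a median log2 fold change of 3.27 and values from 0.68 to 6.47. Further higher runs were 15 tags of the A series (median 2.08), 15 tags of the C series (median 1.67) and 12 tags of the B series (median 2.52). The longest lower run had 10 tags.

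**Figure D2:**
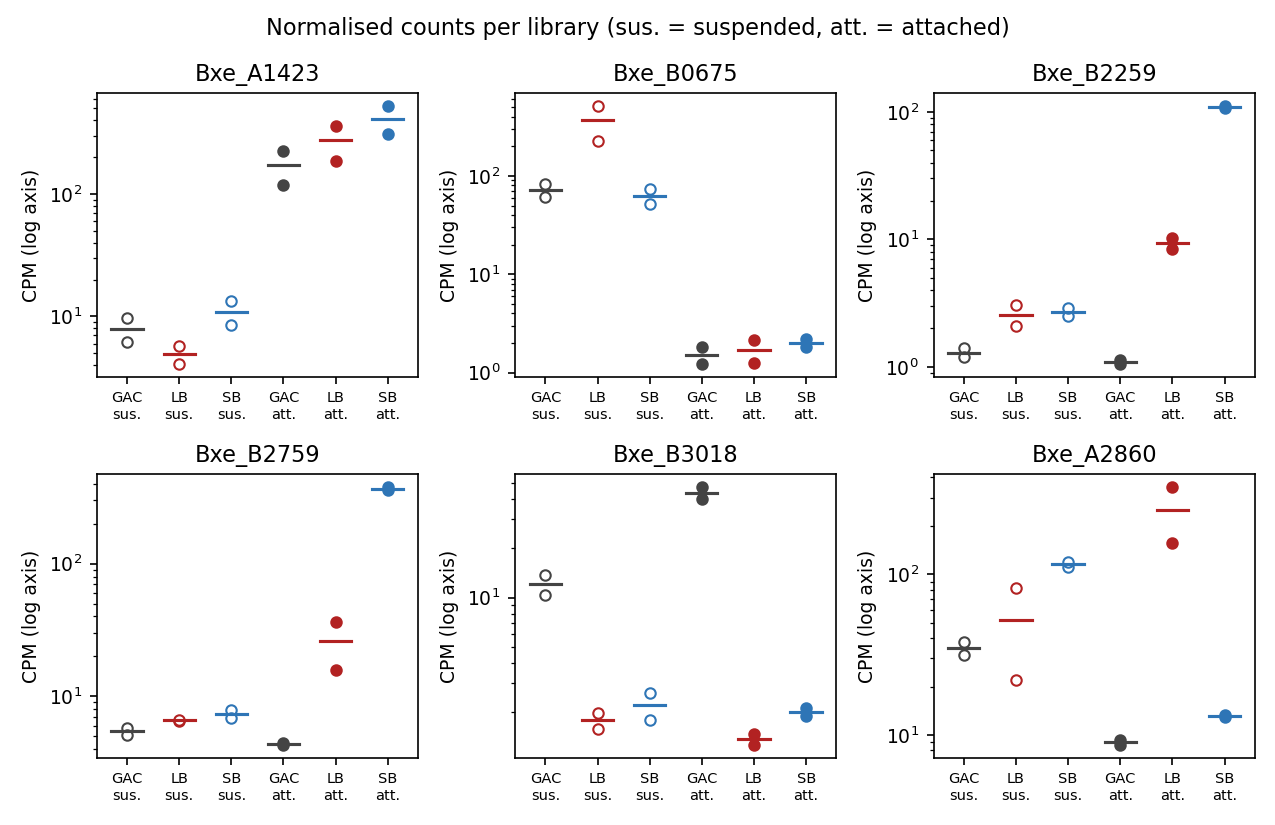
Normalised counts (CPM, log axis) of 6 named tags in suspended (open) and attached (filled) cells with each material, where each circle is a library and each line the mean of 2. Bxe_A1423 is higher and Bxe_B0675 lower in every attached group, Bxe_B2259 and Bxe_B2759 reach 109 and 367 CPM on average in attached SB cells, Bxe_B3018 is highest with GAC, and Bxe_A2860 is highest in attached LB cells.

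Within single materials, 568 tags were higher and 484 lower in attached cells with GAC, 170 and 132 with LB, and 189 and 55 with SB. The share of higher tags with SB depended on the fit. It was 77.5% here, 71.8% with DESeq2 (362 higher, 142 lower) and 61.6% in a fit of the 4 SB libraries alone (829 and 516). With GAC, Bxe_A1423 rose by 4.44 on the log2 scale (SE 0.54, edgeR adjusted p = 0.00322), and with LB by 5.79 (SE 0.57, edgeR adjusted p = 0.00182). Among named tags, the largest rise with SB was that of Bxe_B2757 (log2 fold change 5.76, SE 0.43, edgeR adjusted p = 0.000294). The largest fall with GAC was that of Bxe_A2879 (log2 fold change -6.57, SE 1.78, edgeR adjusted p = 0.046). Alternatives were not computed for either of these results. Bxe_B0675 fell by 7.74 on the log2 scale with LB (SE 0.56, edgeR adjusted p = 0.00079, log2 fold change -7.05 without suspended LB replicate 1) and by 4.96 with SB (SE 0.49, edgeR adjusted p = 0.00181). The effects of different materials share no library, but they come from 1 fit with 1 estimate of the spread per tag. Tags called in both GAC and LB had the same direction in 144 of 147 cases, against 18.5 same-direction tags that independent lists would share. This value is a reference for the overlap, not for the share of matching signs. It leaves out that a tag with a low shared spread is more readily called in both lists, so it may be too low. The matching counts were 111 of 116 for GAC and SB (15.5 for independent lists) and 101 of 102 for LB and SB (4.55). With both LB libraries numbered 1 left out they were 672 of 707 for GAC and LB, 551 of 664 for GAC and SB and 454 of 500 for LB and SB, against 179, 208 and 72.2 for independent lists. Changed in all 3 materials were 35 higher and 27 lower tags, and 9 of the 1295 tags called in any material had opposite directions. Agreement was weaker beyond the tags called in both. Of the tags called with GAC, 75.3% had the same sign with LB and 67.2% with SB. Of those called with LB, 88.1% had the same sign with GAC and 84.1% with SB. Of those called with SB, 84.4% had it with GAC and 89.3% with LB. Log2 fold changes correlated across tags, which are not independent replicates, at 0.439 for GAC and LB, 0.372 for GAC and SB and 0.441 for LB and SB. Spearman's rho was lower, at 0.334, 0.169 and 0.252 in the same order. Without both LB libraries numbered 1 the counts were 2999 with GAC, 1025 with LB and 1201 with SB, the tags changed in all 3 materials were 194 higher and 136 lower, and 162 of 3716 had opposite directions. Without suspended GAC replicate 2 the edgeR adjusted p of Bxe_A1423 with GAC was 0.0571, the highest of its alternatives, which went down to 6.19e-17. The fit of the LB libraries alone called 0 tags (527 at an unadjusted p under 0.05, and 562 changed with DESeq2 on all libraries), with an edgeR adjusted p of 0.375 for both Bxe_A1423 and Bxe_B0675. With the replicate number as a block within each material the counts were 1434 with GAC, 493 with LB (292 higher, 201 lower) and 370 with SB. Leaving out single libraries gave 77 to 1845 tags with GAC, 189 to 748 with LB and 37 to 515 with SB. With GAC, lower tags then outnumbered higher ones without suspended GAC replicate 1 (50 higher, 82 lower) or 2 (22 and 55) and without attached SB replicate 1 or 2 (225 and 242 each), and with LB without suspended LB replicate 1 (229 and 289).

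**Figure D3:**
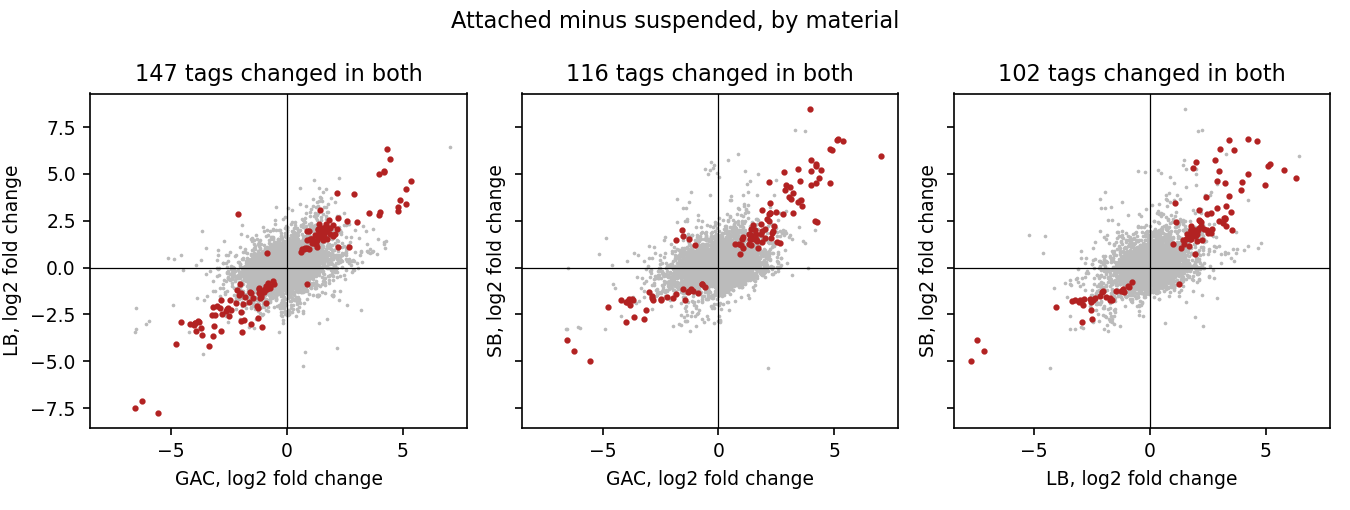
Log2 fold change of attached minus suspended cells in 1 material against another, where each point is a tag and red points passed an adjusted p under 0.05 (edgeR) in both. Of the red points, 144 of 147 (GAC and LB), 111 of 116 (GAC and SB) and 101 of 102 (LB and SB) lie in the lower left or upper right part of the panel, where both signs match.

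The deposited comparison of small kernel biochar with GAC concerns attached cells only. In these, 263 tags were higher and 292 lower with SB. Bxe_B2259 was 98.9-fold higher with SB (log2 fold change 6.63, SE 0.27, edgeR adjusted p = 1.63e-05), at 109 ± 2.24 against 1.09 ± 0.0541 CPM (SD, n = 2 per group). Bxe_B2759 was 84.0-fold higher (log2 fold change 6.39, SE 0.41, edgeR adjusted p = 0.00019), at 367 ± 12.9 against 4.37 ± 0.0987 CPM (SD, n = 2 per group). They lie in runs of 4 and 5 higher tags with log2 fold changes from 5.66 to 6.63 and from 4.60 to 6.39, and a run of 8 tags of the A series was higher by a median of 3.93. Bxe_B3018 fell by 4.43 on the log2 scale (SE 0.27) and its neighbour Bxe_B3017 by 3.62 (SE 0.21), both at an edgeR adjusted p of 0.00019. The longest lower run had 15 tags of the C series, with a median of -1.76. The count of 555 became 2761 without both LB libraries numbered 1, 2094 in a fit of the 4 libraries alone and 1243 with DESeq2. Leaving out single libraries moved it by over 1.5 times for 11 of 12, between 15 without attached SB replicate 2 and 1360 without suspended LB replicate 1, and higher tags then outnumbered lower ones without attached SB replicate 1 (29 and 5) or 2 (11 and 4) and without suspended SB replicate 2 (93 and 91). With the replicate number as a block 93 tags were higher and 59 lower, 152 in all, and without the R-numbered tags 239 were higher and 387 lower. The authors' deposited table calls 1931 tags, 779 higher and 1152 lower, and 529 of these were called here in the same direction.

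In attached cells with large kernel biochar, 571 tags were higher and 650 lower than with GAC. Bxe_A1977 was 29.5-fold higher with LB (log2 fold change 4.88, SE 0.61, edgeR adjusted p = 0.00773), at 65.3 ± 44.6 against 2.21 ± 0.45 CPM (SD, n = 2 per group). Bxe_A2860 was higher by 4.80 on the log2 scale (SE 0.64, edgeR adjusted p = 0.00802), at 252 ± 135 against 9.01 ± 0.486 CPM (SD, n = 2 per group). Leaving out attached LB replicate 1, alone or with the suspended library of that number, lowered these log2 fold changes to 3.94 and 4.13. Bxe_B3018, also lower with SB, fell by 4.99 on the log2 scale (SE 0.28, edgeR adjusted p = 0.000154), and Bxe_B1264 by 4.86 (SE 0.37, edgeR adjusted p = 0.000936). A run of 18 tags of the C series was lower with LB by a median log2 fold change of -2.30 and held all 15 tags of the C-series run that was lower with SB. A run of 13 tags of the B series was lower by a median of -3.85, and a run of 13 tags of the A series was higher by 2.10. The count of 1221 was 1780 without both LB libraries numbered 1 and 1952 with DESeq2, and the fit of the 4 libraries alone called 0 tags (2110 at an unadjusted p under 0.05). Each of the 12 libraries moved it by over 1.5 times when left out, between 39 without attached GAC replicate 1, when the edgeR adjusted p of Bxe_A1977 was 0.0848 and that of Bxe_A2860 0.0889, and 2373 without suspended LB replicate 1. With the replicate number as a block 43 tags were higher and 104 lower, 147 in all, and without the R-numbered tags 476 were higher and 719 lower. The authors' deposited table calls 977 tags, 459 higher and 518 lower, of which 639 were called here in the same direction.

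Both comparisons use the same 2 attached GAC libraries and the same estimate of the spread per tag, neither of which the values for independent lists allow for. They share 125 higher and 211 lower tags, against 17.3 and 21.9 for independent lists, and 5 tags had opposite directions. With both LB libraries numbered 1 left out they share 474 higher and 721 lower tags, against 132 and 151, and 51 had opposite directions. Log2 fold changes correlated across tags at 0.659, against 0.506 in 10 simulations of unchanged groups against shared controls, with a covariance of 0.584 against 0.132. The simulations gave every group the spread pooled over all 12 libraries, a common biological coefficient of variation of 0.322. In attached GAC alone it was 0.19, so the simulated covariance is no exact reference. With 2 control libraries the controls could not be split, so part of the excess may come from them.

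Between the biochars, 67 tags were higher and 25 lower in attached cells for SB minus LB. Bxe_B2260, next to Bxe_B2259, was 18.0-fold higher with SB (log2 fold change 4.17, SE 0.43, edgeR adjusted p = 0.00367), at 97.7 ± 1.63 against 5.42 ± 0.392 CPM (SD, n = 2 per group). Bxe_B2757 was higher by 4.16 (SE 0.40, edgeR adjusted p = 0.00367), at 264 ± 14.1 against 14.7 ± 8.64 CPM (SD, n = 2 per group), and by 4.96 without attached LB replicate 2. Their runs of 4 and 5 tags had median log2 fold changes of 3.71 and 3.82. Bxe_A2860 fell by 4.27 on the log2 scale (SE 0.62, edgeR adjusted p = 0.0175) and Bxe_A1977 fell by 3.83 (SE 0.57, edgeR adjusted p = 0.0205), against log2 fold changes of -3.60 and -2.90 without attached LB replicate 1. All 7 runs were higher with SB. The count of 92 was 501 without both LB libraries numbered 1 and 454 with DESeq2, and the fit of the 4 libraries alone called 0 tags (1072 at an unadjusted p under 0.05). Each of the 12 libraries moved it by over 1.5 times when left out, between 16 without attached SB replicate 2 and 471 without attached LB replicate 2, and the calls of Bxe_A2860 and Bxe_A1977 were lost without either attached GAC or SB library or attached LB replicate 1 (edgeR adjusted p 0.052 to 0.232), that of Bxe_A2860 also without either suspended SB library (0.0515 and 0.0507). With the replicate number as a block 27 tags were higher and 2 lower, 29 in all, and Bxe_A2860 and Bxe_A1977 were not called. The authors' deposited table calls 287 tags, 184 higher and 103 lower, and 90 of them were called here in the same direction.

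In suspended cells, 13 tags were higher and 34 lower for SB minus GAC, 23 and 95 for LB minus GAC, and 38 and 31 for SB minus LB. In the same order, 5, 36 and 3 tags were changed with the replicate number as a block. Bxe_B1264 fell by 5.21 on the log2 scale with SB (SE 0.36, edgeR adjusted p = 0.00165) and fell by 6.44 with LB (SE 0.38, edgeR adjusted p = 0.000495), from 92.5 ± 8.63 CPM with GAC (SD, n = 2). The largest rises of named tags against GAC were those of Bxe_A3388 with SB (log2 fold change 4.72, SE 0.66, edgeR adjusted p = 0.0241) and Bxe_B2298 with LB (6.15, SE 0.72, edgeR adjusted p = 0.00581). Alternatives were not computed for either rise. A run of 6 tags of the A series was lower than with GAC by a median log2 fold change of -3.74 with SB and of -5.90 with LB. With LB, a run of 9 tags of the B series was lower by a median of -4.29. Without both LB libraries numbered 1 the counts were 607, 613 and 882, and with DESeq2 136, 601 and 680, so that SB minus LB had more changed tags in suspended than in attached cells (501 and 454) in both settings, against 69 and 92 with all libraries in edgeR. The majority turned for SB minus GAC without both LB libraries numbered 1 (358 higher, 249 lower) and in the fit of its 4 libraries (453 and 380), for LB minus GAC with DESeq2 (330 and 271), and for SB minus LB with DESeq2 (303 and 377) and without suspended LB replicate 1 (20 and 27). Leaving out single libraries gave between 0 (without suspended SB replicate 1, 445 tags at an unadjusted p under 0.05) and 112, between 21 and 1568, and between 3 and 1498 tags, and the edgeR adjusted p of Bxe_B1264 for SB was 0.0897 and 0.0831 without suspended SB replicate 1 or 2. The fits of the 4 libraries alone called 0 tags for LB minus GAC, where the edgeR adjusted p of Bxe_B1264 was 0.111, and 0 for SB minus LB, with 864 and 962 tags at an unadjusted p under 0.05.

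A value for independent lists is the number of same-direction tags that such lists would share, not a reference for the share of matching signs. It may be too low, since the lists come from 1 fit with a shared spread per tag. The log2 fold changes of SB minus GAC in attached and suspended cells correlated across tags at 0.130 (Spearman's rho -0.06), and 27 of 28 tags called in both fractions had the same direction. Without both LB libraries numbered 1 this was 217 of 321, against 95.7 for independent lists, and 45.5% of the tags called in attached cells had the same sign in suspended cells. For LB minus GAC the correlation was 0.641, and 0.324 without both LB libraries numbered 1. For SB minus LB these values were 0.608 and 0.188. Tests of whether the attachment effect itself differed between materials called 20 tags for SB minus GAC, 2 for LB minus GAC and 25 for SB minus LB, and 1999, 409 and 488 without both LB libraries numbered 1.

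**Figure D4:**
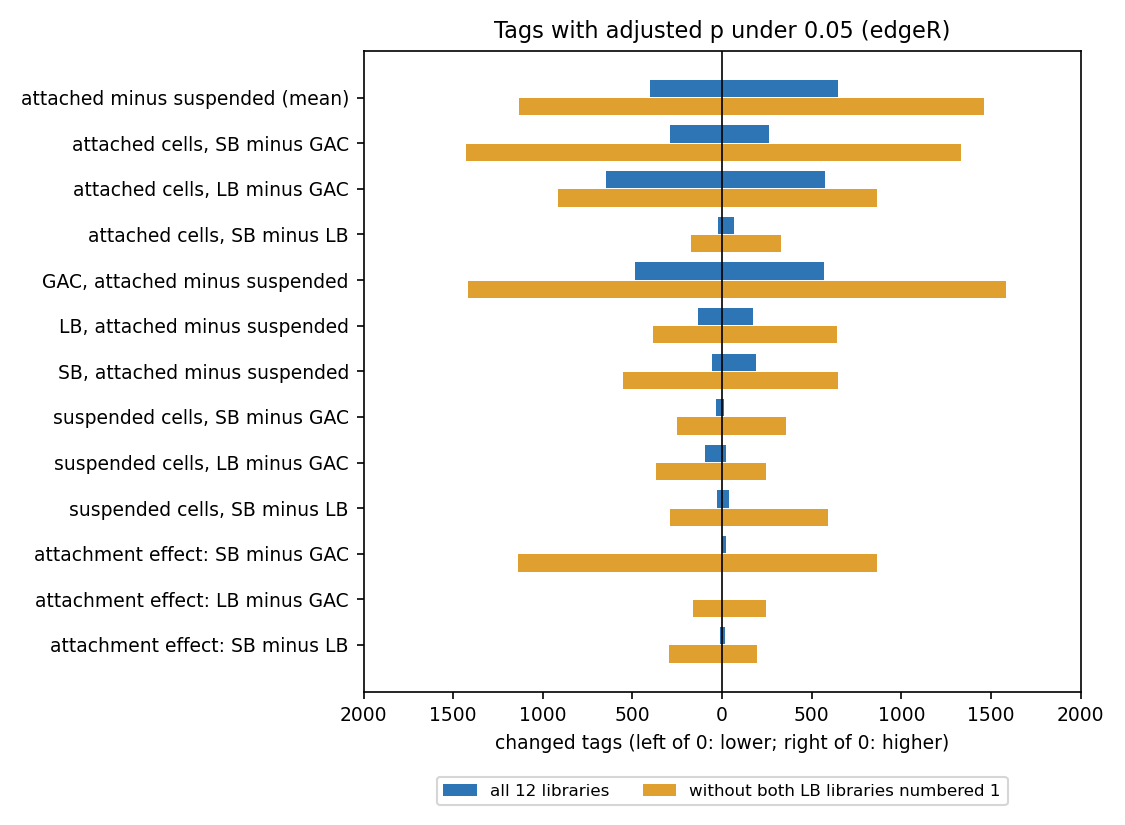
Number of tags with an adjusted p under 0.05 (edgeR) in each of the 13 comparisons, higher tags to the right of 0 and lower tags to the left, with all 12 libraries (blue) and without both LB libraries numbered 1 (orange). The orange bars are the longer ones in each comparison, for example 2592 against 1050 tags for attached minus suspended averaged over the materials.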

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

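The tests of sequencing depth below were set out before their result was seen, and the other tests weighed here were chosen after. Difference tests called 20 tags whose attachment effect was not equal with SB and GAC, 19 of them higher with SB (862 higher and 1137 lower without both LB libraries numbered 1, and 274 and 314 with DESeq2), 2 tags for LB minus GAC and 25 for SB minus LB. For SB minus GAC, the attachment effect of Bxe_B2759 was higher by 5.96 on the log2 scale (SE 0.50, edgeR adjusted p = 0.00411). It was not called without attached GAC replicate 1 (edgeR adjusted p = 0.054) or suspended SB replicate 1 (0.057) or 2 (0.0776), and its alternatives ranged from 1.94e-23 to 0.0776. That of Bxe_B2262 was higher by 5.84 (SE 0.59, edgeR adjusted p = 0.00646), and was not called without attached GAC replicate 1 (0.093) or 2 (0.05), or suspended SB replicate 1 (0.1) or 2 (0.0942). Bxe_B2759 stood at 367 ± 12.9 CPM in attached SB cells and at 7.33 ± 0.696 CPM in suspended ones, against 4.37 ± 0.0987 and 5.43 ± 0.483 CPM with GAC (SD, n = 2 per group). For LB minus GAC the difference for Bxe_A1992 was 4.997 (SE 0.52, edgeR adjusted p = 0.0266), with 5.90 without both LB libraries numbered 1 and 4.38 without attached LB replicate 2. Its mean went from 26.2 ± 9.74 CPM in suspended to 192 ± 92.1 CPM in attached LB cells, and from 1021 ± 75.5 to 235 ± 16.5 CPM with GAC (SD, n = 2 per group). For SB minus LB the differences were 4.60 for Bxe_B2260, 4.29 for Bxe_B2757, -5.41 for Bxe_A2860 and -4.49 for Bxe_A1992, with edgeR adjusted p-values of 0.0361, 0.0361, 0.0498 and 0.0361. Left-out LB libraries moved each by over 1.5 times: Bxe_B2260 to 3.62 without suspended replicate 2, Bxe_B2757 to 5.04 without attached replicate 2, Bxe_A2860 to between -6.66 and -4.75 without suspended replicate 1 or 2, and Bxe_A1992 to -5.43 without both numbered 1. The call for LB minus GAC was lost without any 1 of the GAC or SB libraries (edgeR adjusted p 0.108 to 0.284), as were the 4 for SB minus LB (0.0733 to 0.299), and Bxe_A2860 also lost it without attached LB replicate 1 (0.0568). Bxe_A1992 for LB minus GAC was also not called without the R-numbered tags (0.0705), and its alternatives went down to 1.68e-15. The fit with the replicate number as a block did not call Bxe_A1992 for LB minus GAC either. Bxe_B2759 and Bxe_B2262 lie in runs of 5 and 4 neighbours whose attachment effects were higher for SB minus GAC by medians of 5.48 and 5.36. In attached cells both runs were also higher with LB than with GAC, by medians of 2.17 and 2.32.

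Both LB libraries numbered 1 stood apart from those numbered 2. Lower depth is argued against: with every library thinned to 5537547 counts outside the R-numbered tags, the SD of the log2 difference between LB replicates was 1.08 in attached and 1.26 in suspended cells, against at most 0.524 elsewhere. A swap with a GAC or SB library is argued against as well, since their highest correlation with any of those was 0.89, below the 0.980 of the least similar GAC or SB replicates. A sample from outside the series stays open. A difference of 1 culture that both fractions shared is a candidate explanation, because the deviations of replicate 1 from replicate 2 correlated at 0.622 between attached and suspended LB cells and at no more than 0.14 between materials, while what would have set that culture apart was not tested.

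Leaving out both LB libraries numbered 1 raised the changed tags in attached SB minus GAC, a comparison without LB libraries, from 555 to 2761. The spread between LB replicates in the shared estimate may account for this, since leaving out both LB libraries numbered 2 instead gave 2747 tags, and the common biological coefficient of variation was 0.156 in both cases against 0.322 with all libraries. Leaving out the suspended GAC and SB libraries numbered 1 lowered the count instead. The common biological coefficient of variation then rose to 0.376, so this test does not isolate the number of libraries. Which of these counts lies nearer to the number of tags that differ stays open, as the origin of the LB spread is not known. It may be part of what cultures do, particular to 1 of them, technical, or due to a sample from outside the series.

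For attached minus suspended cells averaged over the materials, 108 splits divide each material's 4 libraries evenly, and 100 were drawn. Of these, 2 gave as many changed tags as the real one, the real split with 1050 included. The highest other split gave 1156 and the median of the others was 0. Other splits mix attached and suspended libraries within a group, which widens the spread and holds counts low. The splits therefore cannot exclude chance assignment. The split with 1156 put both LB libraries numbered 1 on the same side and left the GAC and SB libraries as labelled. Another split of this kind gave 984, which points to that structure of the samples. The fit with the replicate number as a block gave 1383 tags, and without both LB libraries numbered 1 there were 2592.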

How the results depend on the processing

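The settings without LB libraries numbered 1 or 2, without the R-numbered tags, without suspended GAC and SB libraries numbered 1, and the separate fits of the comparisons within 1 material or in suspended cells were chosen after seeing the data. No count moved by over 1.5 times with DESeq2 size factors or without the low-count filter. Alternatives were computed for 29 log2 fold changes of named tags, and none of these reversed under any setting. Size factors moved the share of higher tags from 47.4% to 39.3% for attached SB minus GAC and from 46.8% to 40.9% for LB minus GAC. Leaving out the R-numbered tags under TMM moved these shares to 38.2% and 39.8%. It moved the share for attached minus suspended with GAC from 54% to 59.5%. Counts in the rest of this paragraph follow 1 order: attached minus suspended averaged, then attached SB minus GAC, LB minus GAC and SB minus LB, then attached minus suspended with GAC, LB and SB, then suspended SB minus GAC, LB minus GAC and SB minus LB, then the differences of the attachment effect for SB minus GAC, LB minus GAC and SB minus LB. Without both LB libraries numbered 1 they were 2592, 2761, 1780, 501, 2999, 1025, 1201, 607, 613, 882, 1999, 409 and 488, and all 29 passed the threshold. The Wald test of DESeq2 gave 1416, 1243, 1952, 454, 1536, 562, 504, 136, 601, 680, 588, 395 and 159. Fits of only the libraries compared gave, for the first 10, 352 (with the material left out), 2094, 0, 0, 2673, 0, 1345, 833, 0 and 0. Each 0 is a comparison with the LB libraries, with 2110, 1072, 527, 864 and 962 tags at an unadjusted p under 0.05 in edgeR, and 11 of 22 named results lost their call there. With the replicate number as a block the counts were 1383, 152, 147, 29, 1434, 493, 370, 5, 36, 3, 22, 2 and 61, and attached SB minus GAC had 93 higher and 59 lower tags. Deviations of same-numbered libraries correlated between fractions at 0.622 with LB, but at 0.0077 with GAC and 0.098 with SB, so a pairing by number over all materials was not assumed. For LB, where they correlated, the block within the material gave the 493 tags. Comparisons of materials within a fraction used a block shared by all materials, between which deviations correlated at no more than 0.14. Without the R-numbered tags, suspended SB minus LB had 39 changed tags and the difference for LB minus GAC 0 (1452 at an unadjusted p under 0.05, and 395 with DESeq2 on all tags). Attached SB minus GAC gave 2747 tags without both LB libraries numbered 2 and 12 without the suspended GAC and SB libraries numbered 1, 9 of them higher and 3 lower. Leaving out 1 library leaves its group with a lone library, assumed to vary like the others. The ranges were 548 to 1670, 15 to 1360, 39 to 2373, 16 to 471, 77 to 1845, 189 to 748, 37 to 515, 0 to 112, 21 to 1568, 3 to 1498, 1 to 464, 0 to 817 and 0 to 308, and at each 0 edgeR had between 445 and 1534 tags at an unadjusted p under 0.05. Highest counts came without a suspended LB library, except for attached SB minus LB, where attached LB replicate 2 was left out, and lowest counts came without a GAC or SB library. Of the named results, 11 lost their call without attached GAC replicate 1, and 3 did so with the block: Bxe_A2860 (edgeR adjusted p 0.067) and Bxe_A1977 (0.0753) for attached SB minus LB and Bxe_A1992 for the difference of LB minus GAC (0.0517), with ranges over their alternatives up to 0.198, 0.241 and 0.284. The 4 named results of attached minus suspended averaged, and those of attached SB minus GAC, passed under each of the 19 alternatives computed for them, with adjusted p-values up to 0.0108. The cause of the other moves was not tested. Simulated 2-fold changes between materials in attached cells, drawn with the spread pooled over all 12 libraries, were called in at most 6% of cases. A low count in the fit of all libraries thus does not show that few tags differ. The effect of depth on the counts was not tested. The planned gene lists and the removal of ribosomal and transfer RNA genes were not run, because the files do not pair tags with names.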

Other observations

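The tests in this part were chosen after the result was seen. Runs of neighbouring tags also marked differences that the named tags do not show. The comparisons of attached with suspended GAC cells and of attached biochar with attached GAC cells share the 2 attached GAC libraries with opposite sign, so opposite directions in them are no independent evidence, and no value for unchanged groups was computed for these runs. A run of 12 tags of the C series was higher in attached than in suspended GAC cells by a median log2 fold change of 1.28, and the same tags lie in the run of 15 that was lower in attached cells with SB than with GAC (median -1.76) and in the run of 18 that was lower with LB (median -2.30). A run of 12 tags of the B series was higher in attached than in suspended GAC cells by a median of 3.48, and a run of 13 covering it was lower in attached cells with LB than with GAC by a median of -3.85. A run of 24 tags of the A series was higher in attached SB cells than in suspended ones by a median of 4.57, and shorter runs within it were higher in attached cells with GAC (19 tags, median 3.96) and with LB (7 tags, median 3.03). A run of 14 tags of the C series was higher in attached cells with GAC (median 1.40) and with LB (median 1.98), and 8 of its tags formed a run with SB (median 1.69).

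That neighbouring tags change together was tested by shuffling the calls within each tag letter: 389 changed tags of attached minus suspended cells lay in runs of 4 or more, against at most 13 in 1000 shuffles (permutation p = 0.001, the smallest these can give). Genes read as 1 transcript are a candidate explanation, and strand and gene positions, which could separate this from shared regulation of neighbours, were not analysed here.

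Whether changed tags favour the A, B or C series was tested over 78 combinations of comparison, letter and direction by shifting the calls along the tag order. None passed the correction. The lowest unadjusted p was 0.0034, for 177 higher tags of the A series against 135 by the shifts in attached SB minus GAC, with a Benjamini-Hochberg adjusted p of 0.19.

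With the number 1 libraries set against the number 2 libraries within a material, edgeR called 1103 tags with LB, 698 of them higher in those numbered 1. With GAC and with SB it called 0, with 238 and 176 tags at an unadjusted p under 0.05, and no other tool was run on this contrast.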
